A study of Homo sapiens with 14 samples.

How the data were processed

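Gene expression was measured in MM1S cells, an established human multiple myeloma line that responds to glucocorticoids, after 6 h of treatment. The 14 arrays fall into 7 groups of 2 biological replicates, per the labels: untreated cells, salmeterol at 1 nM, CGS-21680 at 12.5 nM, dexamethasone at a low dose of 25 nM, dexamethasone at a high dose of 2 µM, salmeterol with low dexamethasone, and CGS-21680 with low dexamethasone. Salmeterol is an agonist of the beta-2 adrenergic receptor and CGS-21680 of the adenosine 2A receptor, both of which raise cyclic AMP. Dexamethasone is a synthetic glucocorticoid. The labels call the replicates biological but do not say how the cultures were separated, so the p-values measure the spread between these samples, which may in part be technical. The number of arrays limits the precision of every value.

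The table deposited by the authors holds 1 intensity per probe set and array for 54675 probe sets of an Affymetrix 3' expression array. The submitters' processing notes name GCRMA, which corrects the background, normalizes between arrays and summarises probes into probe sets. Its version and settings are not given in the sources used here. The deposited intensity values run from a shared floor of 4.879 upward with near-equal distributions over the 14 arrays, so they were taken to be on a linear scale and already normalized. That scale is inferred from the values. Between 37.6% and 40.1% of the probe sets of an array had exactly the floor value, which is 2.286 in log2. Expression changes of weakly expressed genes are therefore compressed. Log2 was taken of the deposited values, and no pseudocount was added. Background correction in GCRMA depends on probe sequence. Some values were exactly equal between arrays: 5.2% to 6.19% of the tested genes had the same value in both replicates of a group. Summarising by median polish and the shared floor can both give equal values, and their shares were not counted.

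Probe sets were named through the platform annotation, in which 41097 had 1 gene symbol, 1801 had several and 11777 were not listed. Probe sets with several symbols or none were left out of the comparisons of genes. Of the symbols, 41043 were found by Entrez number in a newer gene table, which changed 0 of them. A probe set entered when its log2 level was at least 4 in at least 2 arrays. Of 15606 such probe sets, the 1 with the highest mean over all arrays stood for its gene, which gave 9301 genes out of 19775 with a named probe set. The choice mattered for 3984 genes with several probe sets past the filter, and for named genes the mean of the probe sets past the filter is given where it ends the call or differs by over 1.5 times. No genome build is named in the sources used here, so no coordinates are given.

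Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings). A single model of 7 group means was fitted to all 14 arrays, so that all groups shared 7 residual degrees of freedom, to which the empirical Bayes step added 2.3. P-values were adjusted by the Benjamini-Hochberg method over the 9301 genes, and a gene counts as changed at an adjusted p under 0.05. All adjusted p-values of single genes come from this limma model. Errors beside log2 differences are standard errors of that model, and errors beside group means are standard deviations of 2 arrays. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, and both arrays of a group lie above or below both of another by chance for 33.3% of genes. Where both arrays of a group lay below a log2 level of 4, the fold between 2 groups is also given as a lower bound against that level. For interactions of such genes, a value with levels below 4 raised to 4 is given, which was added after the results had been seen.

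There were 15 comparisons, of which 6 are described in most detail: each single treatment against untreated cells, and each agonist with low dexamethasone against low dexamethasone alone. The other 9 were each combination against untreated cells, the interaction of each agonist with dexamethasone, high against low dexamethasone, the agonists against each other without and with dexamethasone, and each combination against high dexamethasone. An interaction is the change with the agonist beside low dexamethasone minus the change with the agonist alone.

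The genes named follow a rule set before the data were examined, as were the groups, the comparisons, the gene lists and the alternatives. Tests chosen later are named as such where they are reported. For the 6 comparisons the rule takes, among changed genes whose arrays did not overlap between groups, the 8 largest rises and the 8 largest falls, plus up to 3 changed members of each gene list by smallest adjusted p. For the other 9 it takes the 5 largest rises and falls. It also takes 21 preset genes, of which 16 were measured here. The receptors that the agonists act on were not analysed here.

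The 23 gene lists covered glucocorticoid-induced genes, cyclic AMP and CREB targets, immediate early genes, NF-kappaB targets, the BCL2 family, myeloma and plasma cell genes, MYC and ribosome biogenesis genes, proliferation genes, cyclin-dependent kinase inhibitors, cholesterol synthesis, the unfolded protein response, the amino acid response, the interferon response, heat shock proteins, metallothioneins, the circadian clock, glycolysis and hypoxia genes, phosphodiesterases, receptors and cyclic AMP machinery, and markers of T cells, myeloid cells, stromal cells, and erythroid cells and platelets. The lists were written from general knowledge and not from these samples. The MYC and ribosome biogenesis list is called ribosome biogenesis genes below. It also holds MYC itself and genes with other roles, such as the transferrin receptor gene TFRC. HSPE1 is on this list and on the heat shock list. The 20 lists with at least 5 tested genes were tested with camera, which compares a list with all other genes, at its preset correlation between genes of 0.01. Camera with a correlation estimated from the data was run beside it, and fry, which asks whether the genes of a list move on balance in 1 direction.

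The procedure was tested on simulated data drawn around the real levels, with 50 genes changed at each of 4 sizes. For salmeterol against untreated cells, over 9301 genes, it recovered 26% of genes changed 1.5-fold, 74% of those changed 2-fold, 98% at 4-fold and 100% at 8-fold, with 9 unchanged genes called. For the salmeterol interaction it recovered 8%, 32%, 84% and 100%, with 2 unchanged genes called. A simulated shift of 0.3 in the proliferation list for salmeterol against untreated cells was recovered by camera at adjusted p = 1.06e-11, with 0 of the other lists called. The simulated spread was independent between genes, so this does not show how camera acts on lists whose genes move together. In the real arrays the estimated correlation within the proliferation list was 0.166.

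The alternatives tried were no filter and a stricter filter (log2 level of at least 6), the mean of a gene's probe sets, a further quantile normalization, limma's variance trend with robust moderation, the replicate number as a block, a fit of only the arrays of each comparison, and leaving out each array in turn. Leaving out an array leaves its group with 1 array, which is then assumed to vary like the other groups. Comparisons that share control arrays share their chance values, so simulated values for unchanged groups against the same controls are given beside correlations between them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.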

Results

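MM1S multiple myeloma cells were profiled on 14 arrays after 6 h with a beta-2 adrenergic agonist (salmeterol), an adenosine 2A receptor agonist (CGS-21680), a glucocorticoid (dexamethasone at 25 nM or 2 µM), or an agonist together with 25 nM dexamethasone. The study's title asks what the agonists do in combination with dexamethasone. Each group held 2 arrays, and 9301 genes were compared. The median log2 level of these genes ranged from 7.437 to 7.631 over the arrays, and replicates correlated at 0.9868 to 0.9919 across genes. High dexamethasone replicate 2 had the lowest mean of the spiked control probe sets, 13.1 in log2, and the lowest difference between the 3' and 5' GAPDH control probe sets, 0.735 against 0.887 to 1.31 on the other arrays. The high dexamethasone pair had the widest spread between replicates (SD of the differences 0.365 in log2, against 0.286 to 0.341 in the other pairs). Control probe sets also differed within other pairs. The 18S ribosomal RNA control had log2 levels of 9.069 and 11.21 on untreated replicates 1 and 2, the latter the highest of all arrays. The difference between the 3' and 5' ACTB control probe sets was 1.25 and 2.23 on CGS-21680 replicates 1 and 2, the lowest and highest of all arrays. Unless an array is named beside it, a single gene from the naming rule that is reported below as having risen or fallen also passed the test in each of the 14 fits that left out 1 array and in which it passed the filter. Of the genes named, WFDC21P, MT1H and IRAK2 did not pass the filter without either array of salmeterol with dexamethasone, and TMEM65 not without either untreated array, so they were not tested there.

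**Figure D1:**
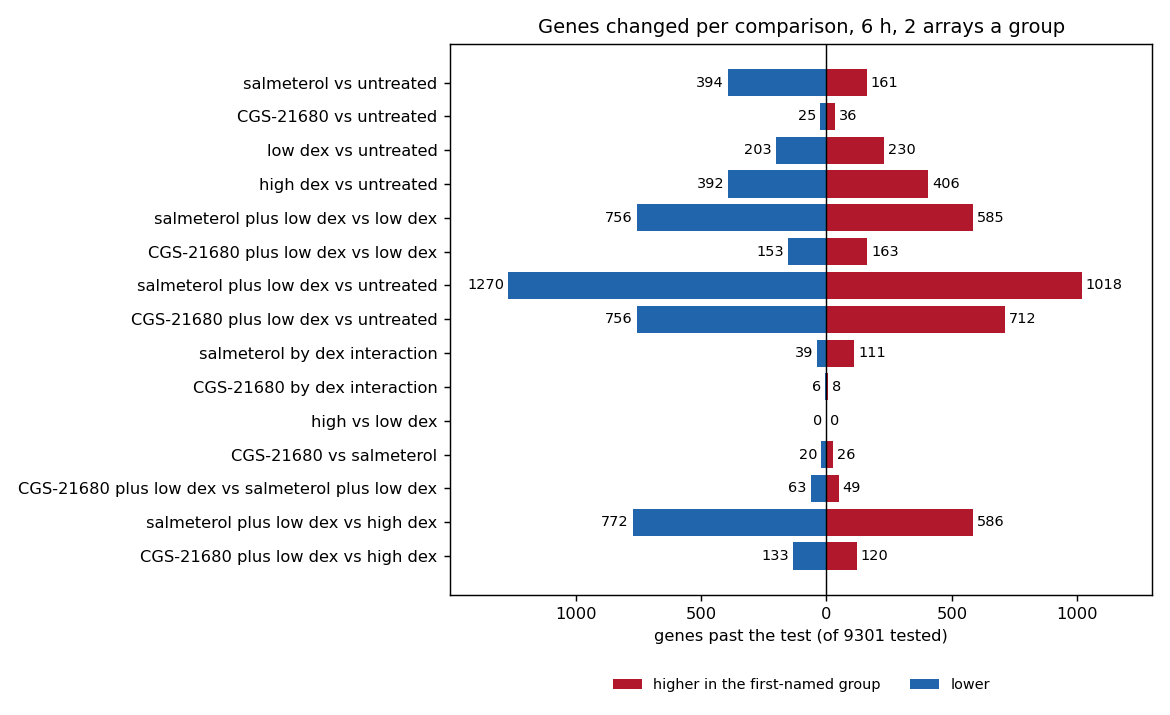
Genes past the limma test in each of the 15 comparisons, of 9301 tested; red bars count genes higher and blue bars genes lower in the first-named group. Salmeterol with low dexamethasone against low dexamethasone alone changed 1341 genes, and salmeterol alone against untreated cells changed 555.

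Salmeterol alone changed 555 of 9301 genes, 161 of them higher and 394 lower, and 220 by at least 2-fold. The largest rises were in FBXO32, a ubiquitin ligase subunit, which went from a log2 level of 6.51 ± 0.53 in untreated cells to 12.55 ± 0.17 (SD, n = 2), a difference of 6.04 ± 0.30 (adjusted p = 1e-05; 3.15 for the mean of its 6 probe sets), and in SAT1, the acetyltransferase that starts polyamine breakdown (5.76 ± 0.225, adjusted p = 2.8e-06). STAT4, a cytokine-activated transcription factor, rose by 5.52, the calcium-binding protein gene TESC by 5.32 ± 0.126 (adjusted p = 5.6e-08), the dynein assembly factor gene DNAAF1 by 5.10 (2.59 for the mean of its probe sets) and the chemokine gene CXCL10 by 4.44. Among the largest falls were C11orf96 (−3.25), the deacetylase gene HDAC9 (−3.24 ± 0.368, adjusted p = 0.0014), the pyrimidine catabolic gene DPYD (−2.95, at least 3.04-fold), the integrin gene ITGA4 (−2.82) and FRMD6 (−2.80). The chemokine gene CCL4 had the largest fall, −3.45, which did not pass without untreated replicate 1 (adjusted p = 0.0625). DDIT4 rose by 2.57, and did not pass without the same array (adjusted p = 0.0527).

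Of the cyclic AMP and CREB targets, 5 of 25 tested rose with salmeterol and 3 fell (7 and 5 adjusted over the list alone). PDE4B, a phosphodiesterase that degrades cyclic AMP, rose by 3.37 ± 0.342 (adjusted p = 0.0007), CREM, a repressor of CREB targets, by 3.01 and the G-protein regulator gene RGS2 by 2.23 ± 0.113, while NFIL3 fell by 1.07 on the log2 scale. The list lay higher than other genes at camera's preset correlation (adjusted p = 0.00671), but not with its own (adjusted p = 0.193 with an estimated correlation). Phosphodiesterases (3 of 9 higher, 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.154 with an estimated correlation) and receptors and cyclic AMP machinery (3 of 27 higher, 3 adjusted over the list alone, adjusted p = 0.129 with an estimated correlation) behaved likewise. In the second of these lists RGS1, another regulator of G-protein signalling, rose by 3.58 ± 0.174.

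Genes of myeloma and plasma cells went the other way with salmeterol, with 7 of 32 lower and 3 higher (12 and 4 adjusted over the list alone; median −0.292; camera adjusted p = 0.00987, and adjusted p = 0.251 with an estimated correlation). IRF4, a transcription factor on which myeloma cells depend, fell from 11.91 ± 0.033 to 10.23 ± 0.097 (SD, n = 2), a difference of −1.68 ± 0.108 (adjusted p = 4.8e-05). TNFRSF17, the plasma cell receptor BCMA, fell by 1.73 on the log2 scale and CD48 by 1.41. MYC did not pass (−0.36 ± 0.123, adjusted p = 0.13). In the BCL2 family, the BH3-only genes BCL2L11, which encodes BIM, and BMF rose by 1.55 ± 0.112 (adjusted p = 8.8e-05) and 0.72, and the list of 12 as a whole did not pass (2 higher and 2 lower, also adjusted over the list alone, camera adjusted p = 0.645). The 2 lower in the fit of all arrays were PMAIP1, also a BH3-only gene, and the survival gene MCL1. MCL1 did not pass with the mean of its probe sets (adjusted p = 0.361). It also did not pass without untreated replicate 1 or 2, or without salmeterol replicate 1 or 2.

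The proliferation list shifted upward with salmeterol by a median of 0.328 over 36 genes (camera adjusted p = 8.69e-11, and adjusted p = 0.129 with an estimated correlation), although only 3 members passed singly (5 adjusted over the list alone). Camera also placed glucocorticoid-induced genes (5 of 25 higher, 3 lower; adjusted p = 0.193 with an estimated correlation), metallothioneins (0 of 8 past the test; adjusted p = 0.129 with an estimated correlation) and glycolysis and hypoxia genes (4 of 25 higher; adjusted p = 0.129 with an estimated correlation) higher, and ribosome biogenesis genes (2 of 35 lower; adjusted p = 0.129 with an estimated correlation) lower. Adjusted over the list alone these counts were 5 and 4, 1 higher, 4 higher, and 4 lower. The 4 glycolysis and hypoxia genes were DDIT4, VEGFA, GAPDH and LDHA. VEGFA went to −0.0697 with the mean of its probe sets. GAPDH did not pass without either untreated or either salmeterol array, and DDIT4 not without untreated replicate 1. Leaving out single arrays lowered the count of changed genes to 213 without untreated replicate 1, 231 without untreated replicate 2, 359 without salmeterol replicate 1 and 296 without salmeterol replicate 2. A further quantile normalization gave 218 higher and 291 lower, so that the share of higher genes went from 29% to 42.8%.

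CGS-21680 alone changed 61 genes, 36 higher and 25 lower. STAT4 rose by 4.22 ± 0.287 (adjusted p = 0.00029) and TESC by 3.55 ± 0.126 (adjusted p = 2.3e-06). FBXO32 rose by 3.21, SAT1 by 2.99, DNAAF1 by 2.87 and RGS1 by 2.79 ± 0.174. For FBXO32, 1 of 6 probe sets had the opposite sign and their mean gave 1.04, and the mean for DNAAF1 gave 1.45. The adaptor gene SH2B2 fell by 1.30 ± 0.127 on the log2 scale (adjusted p = 0.0026) and TMEM65 by 0.97, at least 1.33-fold. CXCL10 rose by 3.35, and did not pass without CGS-21680 replicate 1 (adjusted p = 0.0713) or replicate 2 (adjusted p = 0.0564), or with no filter (adjusted p = 0.0549). BCL2L11 rose by 0.97 ± 0.112 (adjusted p = 0.0065) and TNFRSF17 fell by 1.14 on the log2 scale, and neither passed without untreated replicate 1 (adjusted p = 0.072 and 0.0505) or replicate 2 (adjusted p = 0.0579 and 0.0626). With the mean of its probe sets BCL2L11 had 0.61 (adjusted p = 0.531). IRF4 fell by 0.83 on the log2 scale (adjusted p = 0.011), and did not pass without untreated replicate 1 (0.0863), untreated replicate 2 (0.0835) or CGS-21680 replicate 2 (0.0574).

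Among gene lists, the proliferation genes shifted upward with CGS-21680 by a median of 0.337, with 0 of 36 members past the limma test over all genes and 10 higher adjusted over the list alone (camera adjusted p = 1.27e-11, and adjusted p = 0.296 with an estimated correlation). Phosphodiesterases lay higher (median 0.602; 1 of 9 past the test and 4 adjusted over the list alone; adjusted p = 0.372 with an estimated correlation). Immediate early genes (0 of 15, and 3 lower adjusted over the list alone; adjusted p = 0.372 with an estimated correlation) and myeloma genes (2 of 32 lower and 1 higher, against 5 and 3 adjusted over the list alone; adjusted p = 0.459 with an estimated correlation) lay lower. The count of genes fell to 11 without untreated replicate 1 and 17 without untreated replicate 2, and the number of lists called by camera to 1 without CGS-21680 replicate 1 and 2 without untreated replicate 2.

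Set directly against salmeterol, CGS-21680 gave 46 genes at different levels, 26 higher and 20 lower. SAT1 was lower by −2.77 ± 0.225 (adjusted p = 0.0019) and PIGF, a gene of lipid anchor synthesis, higher by 1.78 ± 0.149, though its probe sets averaged 0.96 (adjusted p = 0.0788). FBXO32 (−2.83) and DNAAF1 (−2.23, or −1.14 for the mean of its probe sets) were lower too, but without CGS-21680 replicate 1 both had an adjusted p of 0.0544. The count was 8 without CGS-21680 replicate 1, 24 without CGS-21680 replicate 2, 26 without either untreated array and 70 without salmeterol replicate 1, and quantile normalization changed the split to 17 higher and 29 lower. The doses were 1 nM and 12.5 nM, and no dose series was run. Over the 1341 genes that salmeterol changed beside dexamethasone, on other arrays, the median change in that direction was 0.359 with salmeterol alone (95% bootstrap interval 0.337 to 0.384) and 0.163 with CGS-21680 alone (0.144 to 0.177), both against the same untreated arrays. Those genes were picked for a response to salmeterol, which favours it. Over the 61 genes that CGS-21680 alone changed, the median change in that direction beside dexamethasone, on other arrays, was 1.35 with salmeterol (0.949 to 1.59) and 0.797 with CGS-21680 (0.678 to 1.12). The changes with the agonists correlated across genes at 0.738, where unchanged groups against the same controls gave 0.503. Their covariance was 0.0895 against a simulated 0.0222. There were 32 genes higher and 25 lower with both, against 0.623 and 1.06 for independent lists, and part of that excess may come from the shared controls. Genes are not independent replicates.

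Low dexamethasone changed 433 genes, 230 higher and 203 lower. DDIT4, an inhibitor of mTOR signalling, rose from 5.19 ± 0.38 to 13.45 ± 0.11 (SD, n = 2), a difference of 8.26 ± 0.389 (adjusted p = 6.3e-06). TSC22D3, the glucocorticoid-induced leucine zipper gene, rose by 6.03 ± 0.245 (adjusted p = 2.7e-06) and FKBP5, a chaperone of the glucocorticoid receptor, by 3.98 ± 0.08 (adjusted p = 1.2e-08). NUDT16 rose by 3.99 (2.02 for the mean of its 4 probe sets), FBXO32 by 3.62, the prolyl hydroxylase gene P4HA1 by 3.55, FAR2 by 3.27 and the chemokine receptor gene CXCR4 by 2.89. STON2 fell by 3.55 ± 0.108 on the log2 scale (at least 3.7-fold), the transferrin receptor gene TFRC by 2.36, IGFBP3 by 2.35, FRMD6 by 2.31 and ITGA8 by 1.90.

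Of the glucocorticoid-induced genes, 15 of 25 rose and 1 fell (18 and 1 adjusted over the list alone; median 0.97; camera adjusted p = 1.05e-21, and adjusted p = 0.00141 with an estimated correlation). The gene that fell, named after its values were seen, was SGK1 (−0.60 ± 0.128, adjusted p = 0.0298). The MYC and ribosome biogenesis list went down, with 8 of 35 genes past the test over all genes and 28 adjusted over the list alone. Its median was −0.564 (camera adjusted p = 0.0016 with an estimated correlation). The 8 in the fit of all arrays were TFRC, LYAR, DDX21, NOP2, WDR3, SLC19A1, HSPE1 and SRM. LYAR lay at −1.42 ± 0.121 (−0.92 for the mean of its probe sets) and WDR3 at −0.81 ± 0.0951. Heat shock genes fell in 8 of 15 cases, 12 adjusted over the list alone (median −0.547; adjusted p = 0.00723 with an estimated correlation), among them HSPA4L (−1.10) and HSP90AA1 (−0.90). BMF rose by 1.86 ± 0.109 (adjusted p = 2.2e-05) and BCL2L11 by 1.00 ± 0.112 (adjusted p = 0.0013; 0.80 with adjusted p = 0.112 for the mean of its probe sets), while IRF4 fell by 1.06 and the cyclin gene CCND2 by 1.09 on the log2 scale. The survival gene BCL2 also passed as higher in the fit of all arrays (0.93). It did not pass with the mean of its probe sets (0.38, adjusted p = 0.0973) or with no filter (adjusted p = 0.0915). Without untreated replicate 1 or 2 or low dexamethasone replicate 2 it did not pass either. MYC did not pass (−0.46 ± 0.123, adjusted p = 0.074), but did after quantile normalization (adjusted p = 0.0466), with the variance trend and robust moderation (0.049) and with the replicate block (0.0461).

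Camera called 4 more lists with low dexamethasone at the preset correlation and none of these with an estimated one. They were cyclic AMP targets (2 of 25 higher, 1 lower; adjusted p = 0.371 with an estimated correlation), stromal markers (1 of 5 higher; adjusted p = 0.222 with an estimated correlation), cholesterol synthesis (1 of 18 lower; adjusted p = 0.41 with an estimated correlation) and the amino acid response (2 of 28 higher, 5 lower; adjusted p = 0.371 with an estimated correlation). Adjusted over the list alone these were 5 and 1, 1, 1, and 2 and 6. The amino acid list had a median of −0.137 but a mean of 0.0616, since it includes DDIT4. The count of changed genes was 187 without untreated replicate 1, 221 without untreated replicate 2, 191 without low dexamethasone replicate 1 and 204 without low dexamethasone replicate 2, and the count of lists was 4 without untreated replicate 1 or low dexamethasone replicate 2.

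High dexamethasone changed 798 genes, 406 higher and 392 lower. DDIT4 (8.68 ± 0.389), TSC22D3 (6.47 ± 0.245), NUDT16 (4.94 ± 0.47), FKBP5 (4.15 ± 0.08, adjusted p = 8.4e-09) and P4HA1 (3.99 ± 0.277) rose most, with the B cell chemokine gene CXCL13 at 3.90 ± 0.383, at least 6.63-fold. STON2 (−3.59, at least 3.7-fold), TFRC (−3.07), GJA1 (−2.72), MCC (−2.69), FRMD6 (−2.46) and CBLN2 (−2.23) fell. The mean of the probe sets gave 2.59 for NUDT16, −1.88 for TFRC and −1.68 for MCC. MYC fell by 0.82 ± 0.123 (adjusted p = 0.0038), IRF4 by 1.26 ± 0.108 (adjusted p = 2e-04), CCND2 by 1.29 and the survival gene BCL2L1 by 1.44 on the log2 scale, while BMF rose by 2.00 and BCL2L11 by 1.25 ± 0.112 (adjusted p = 0.00024). The survival gene BCL2 passed as higher in the fit of all arrays (0.77), with 1 of 4 probe sets of opposite sign. It did not pass with their mean (0.23, adjusted p = 0.253) or with no filter (adjusted p = 0.122). The glucocorticoid-induced list had 18 of 25 higher and 1 lower (19 and 1 adjusted over the list alone; adjusted p = 0.00135 with an estimated correlation). Ribosome biogenesis genes had 20 of 35 lower (32 adjusted over the list alone; median −0.705; adjusted p = 0.00135 with an estimated correlation) and heat shock genes 10 of 15 (12 adjusted over the list alone; adjusted p = 0.0126 with an estimated correlation). Cyclic AMP targets (5 of 25 higher, 1 lower, against 7 and 1 adjusted over the list alone) were called at the preset correlation, and had adjusted p = 0.454 with an estimated correlation. The gene count was 342 without untreated replicate 1, 396 without untreated replicate 2 and 388 without high dexamethasone replicate 2.

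Between high and low dexamethasone, limma called 0 genes at different levels, with 328 at an unadjusted p under 0.05. It called 14 with no filter, 1 with the mean of a gene's probe sets, 60 without high dexamethasone replicate 1 and 2 without high dexamethasone replicate 2. Over 902 genes that low dexamethasone changed in the same direction beside salmeterol and beside CGS-21680, on other arrays, the median change in that direction was 0.503 at the low dose and 0.596 at the high dose. The median difference between the doses in that direction was 0.0891, with a 95% bootstrap interval over genes of 0.0745 to 0.097. That interval treats genes as independent, which they are not, and leaves out the spread between arrays. The changes at the doses correlated at 0.894 across genes, against 0.481 for unchanged groups with the same controls, with a covariance of 0.175 against 0.0213. There were 207 genes higher and 182 lower at both doses, against 10 and 8.56 for independent lists, part of which may come from the shared untreated arrays. TSC22D3 differed by 0.44 (adjusted p = 1) and MYC by −0.36 (adjusted p = 1).

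**Figure D2:**
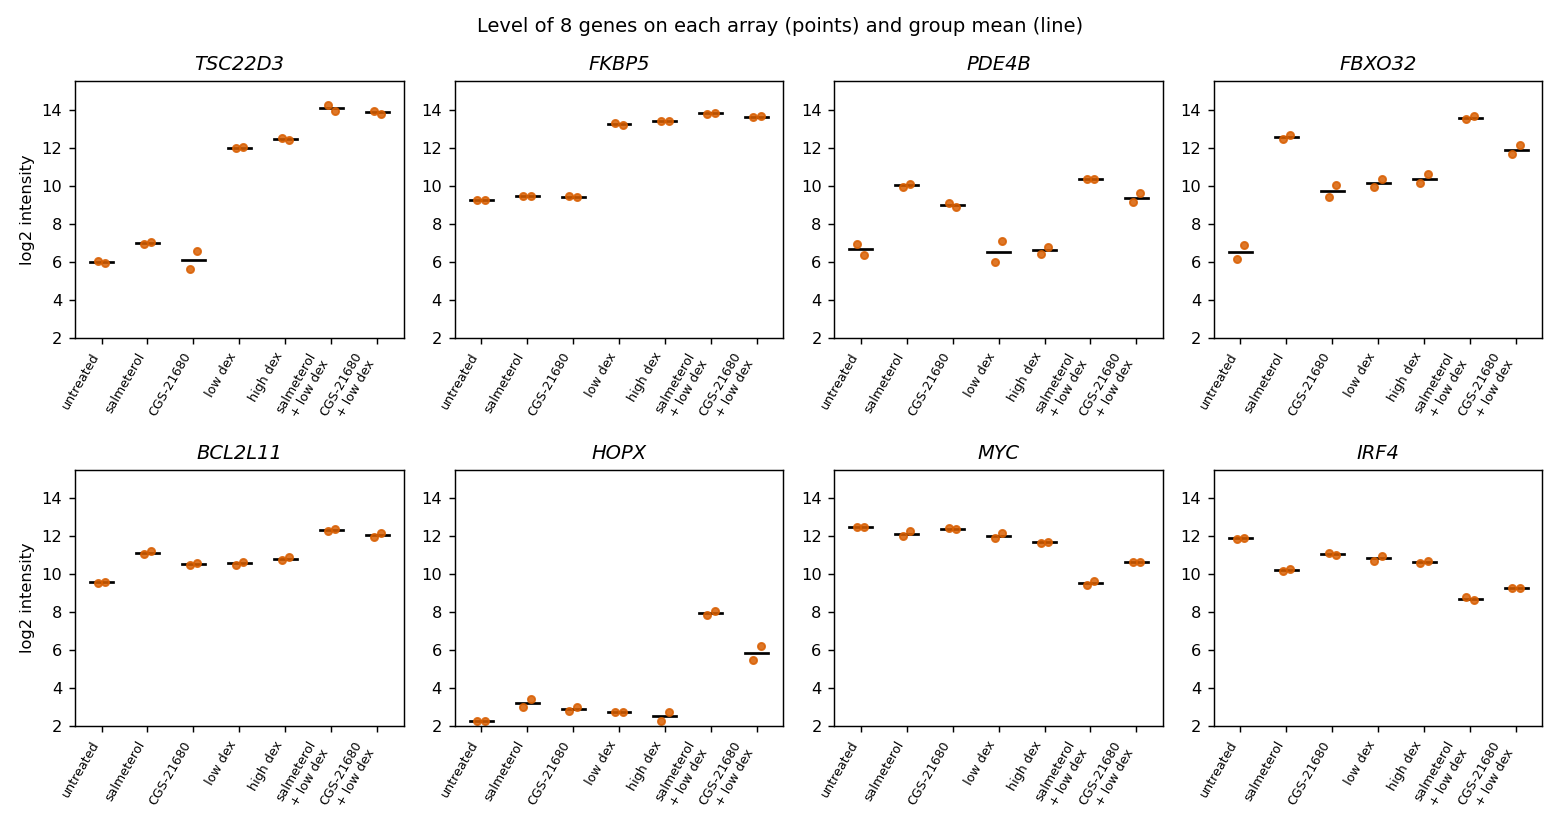
Log2 level per array (points) and group mean (bar) of genes named in the report across the 7 groups, 2 arrays each. MYC has a mean of 12.5 in untreated cells, 12.04 with low dexamethasone, 12.14 with salmeterol and 9.53 with both.

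Added to low dexamethasone, salmeterol changed 1341 genes against low dexamethasone alone, 585 higher and 756 lower, and 482 by at least 2-fold. DNAAF1 rose by 7.36 ± 0.24 (adjusted p = 5.5e-07; 3.73 for the mean of its probe sets), STAT4 by 6.55, TESC by 5.98 ± 0.126 and SAT1 by 5.40. Genes at or near the floor in low dexamethasone also rose: FGL2, which encodes a fibrinogen-like protein of immune cells, by 7.20 ± 0.389 (at least 48.7-fold, adjusted p = 5.5e-06), the pseudogene transcript WFDC21P by 5.76 (at least 16.5-fold) and the homeodomain protein gene HOPX by 5.19 ± 0.245 (at least 15.6-fold). The sulfotransferase gene CHST2 rose by 4.67. C11orf96 (−3.92, at least 9.35-fold), HDAC9 (−3.72), CCL4 (−3.63), RASGRP3 (−2.99), the chemokine receptor gene CX3CR1 (−2.98), DPYD (−2.89, at least 3.05-fold), ITGA8 (−2.76) and the mTOR inhibitor gene DEPTOR (−2.72) fell.

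Myeloma genes fell with salmeterol beside dexamethasone, 15 of 32 lower and 2 higher (16 and 3 adjusted over the list alone; median −0.744; camera adjusted p = 2.51e-08, and adjusted p = 0.0452 with an estimated correlation). MYC went from 12.04 ± 0.2 to 9.53 ± 0.14 (SD, n = 2), a difference of −2.52 ± 0.123 (adjusted p = 3.7e-06). IRF4 fell by 2.12 ± 0.108 (adjusted p = 5e-06; −1.14 for the mean of its probe sets), the myeloma transcription factor gene MAF by 1.70 ± 0.23 (adjusted p = 0.0013) and SDC1, the plasma cell surface marker CD138, by 1.64 ± 0.109 on the log2 scale. Ribosome biogenesis genes had 20 of 35 lower (28 adjusted over the list alone; median −0.729; adjusted p = 0.00447 with an estimated correlation), with WDR3 at −1.75 and DDX21 at −1.33. The proliferation list lay higher (8 of 36 higher and 1 lower, against 10 and 1 adjusted over the list alone; median 0.268; adjusted p = 0.244 with an estimated correlation), MCM6 by 0.92 and PCNA by 0.83.

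Of the cyclic AMP targets 14 of 25 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.776; adjusted p = 0.0452 with an estimated correlation). They included PDE4B at 3.82 ± 0.342, PDE3B at 3.47 (at least 6.42-fold), CREM at 2.02, RGS2 at 1.93 and the orphan receptor gene NR4A1 at 0.78 (0.50 for the mean of its probe sets). Phosphodiesterases had 6 of 9 higher and 1 lower, the same adjusted over the list alone (median 1.52; adjusted p = 0.0516 with an estimated correlation). Glucocorticoid-induced genes rose above their level with dexamethasone alone in 12 of 25 cases and fell in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.0305 with an estimated correlation). SGK1, a kinase gene, rose by 2.75 ± 0.128 (adjusted p = 2.7e-06), TSC22D3 by 2.09 ± 0.245 (adjusted p = 0.00054), the phosphatase gene DUSP1 by 1.10 (0.56 for the mean of its probe sets) and FKBP5 by 0.57 ± 0.08 (adjusted p = 0.0873 for the mean of its probe sets).

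Metallothioneins, metal-binding proteins, had 3 of 8 higher, also adjusted over the list alone (adjusted p = 0.0452 with an estimated correlation): MT1X by 2.47 ± 0.152, MT2A by 2.13 and MT1H by 1.43 (at least 1.32-fold). Stromal markers had 2 of 5 higher, also adjusted over the list alone (adjusted p = 0.101 with an estimated correlation), namely the intermediate filament gene VIM (3.05 ± 0.173) and the fibronectin gene FN1 (2.03). In the BCL2 family, BCL2L11 rose by 1.77 ± 0.112 (adjusted p = 1.4e-05) and the BH3-only gene PMAIP1 by 1.58 (at least 2.21-fold), BCL2L1 fell by 1.16 on the log2 scale (−0.71 for the mean of its probe sets), and MCL1 (−0.22, adjusted p = 0.12, or 0.0455 with no filter) and BCL2 (−0.36, adjusted p = 0.28) did not pass. The DNA damage gene GADD45A rose by 3.38 ± 0.19. The gene count was 824 without low dexamethasone replicate 1, 758 without low dexamethasone replicate 2 and 725 without the combination's replicate 1.

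CGS-21680 added to low dexamethasone changed 316 genes, 163 higher and 153 lower. STAT4 rose by 5.45 ± 0.287, DNAAF1 by 5.12, TESC by 4.27 ± 0.126 (adjusted p = 4.2e-07) and RGS1 by 3.19. Further rises were in the fibrillin gene FBN1 (3.14 ± 0.177, adjusted p = 3.3e-05), HOPX (3.08, at least 3.61-fold), VIM (2.20) and GADD45A (1.99). OSBPL1A fell by 2.07 ± 0.223 on the log2 scale (adjusted p = 0.0013), LINC00582 by 1.83 and IRAG2 by 1.78. The mean of the probe sets gave −1.19 for OSBPL1A, 2.56 for DNAAF1 and −1.02 for IRF4. C11orf96 (−3.00) and HDAC9 (−2.47) fell too, but both had an adjusted p of 0.0601 without low dexamethasone replicate 1, and of 0.07 and 0.0623 without replicate 2. TSC22D3 rose by 1.85 ± 0.245 (adjusted p = 0.0042) and BCL2L11 by 1.49 ± 0.112 (adjusted p = 0.00022). MYC fell by 1.39 ± 0.123 (adjusted p = 0.00042), IRF4 by 1.55 ± 0.108 (adjusted p = 0.00013) and TNFRSF17 by 1.30 on the log2 scale, and MAF did not pass (−0.97 ± 0.23, adjusted p = 0.057). MAF did pass with the stricter filter (adjusted p = 0.0383), the mean of its probe sets (0.00132), quantile normalization (0.0357), the variance trend (0.0379) and the replicate block (0.0374), and without replicate 2 of the combination (0.00907).

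Ribosome biogenesis genes had 11 of 35 lower (19 adjusted over the list alone; median −0.529; adjusted p = 0.00282 with an estimated correlation) and glucocorticoid-induced genes 7 of 25 higher and 1 lower (9 and 1 adjusted over the list alone; median 0.379; adjusted p = 0.0325 with an estimated correlation). Called at the preset correlation alone were cyclic AMP targets (7 of 25 higher; adjusted p = 0.0555 with an estimated correlation), phosphodiesterases (4 of 9 higher; adjusted p = 0.0555 with an estimated correlation), myeloma genes (7 of 32 lower, 1 higher; adjusted p = 0.0555 with an estimated correlation) and proliferation genes (4 of 36 higher; adjusted p = 0.164 with an estimated correlation). The same held of metallothioneins (0 of 8; adjusted p = 0.113 with an estimated correlation), stromal markers (1 of 5 higher, VIM; adjusted p = 0.113 with an estimated correlation) and the unfolded protein response. That last list lay lower (median −0.136; adjusted p = 0.45 with an estimated correlation), and its 1 changed member of 24, also adjusted over the list alone, was higher. Adjusted over the list alone the other counts were 8, 5, 10 and 1, 8, 2 and 1. The gene count was 99 without low dexamethasone replicate 1, 128 without low dexamethasone replicate 2, 198 without the combination's replicate 1 and 163 without its replicate 2.

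**Figure D3:**
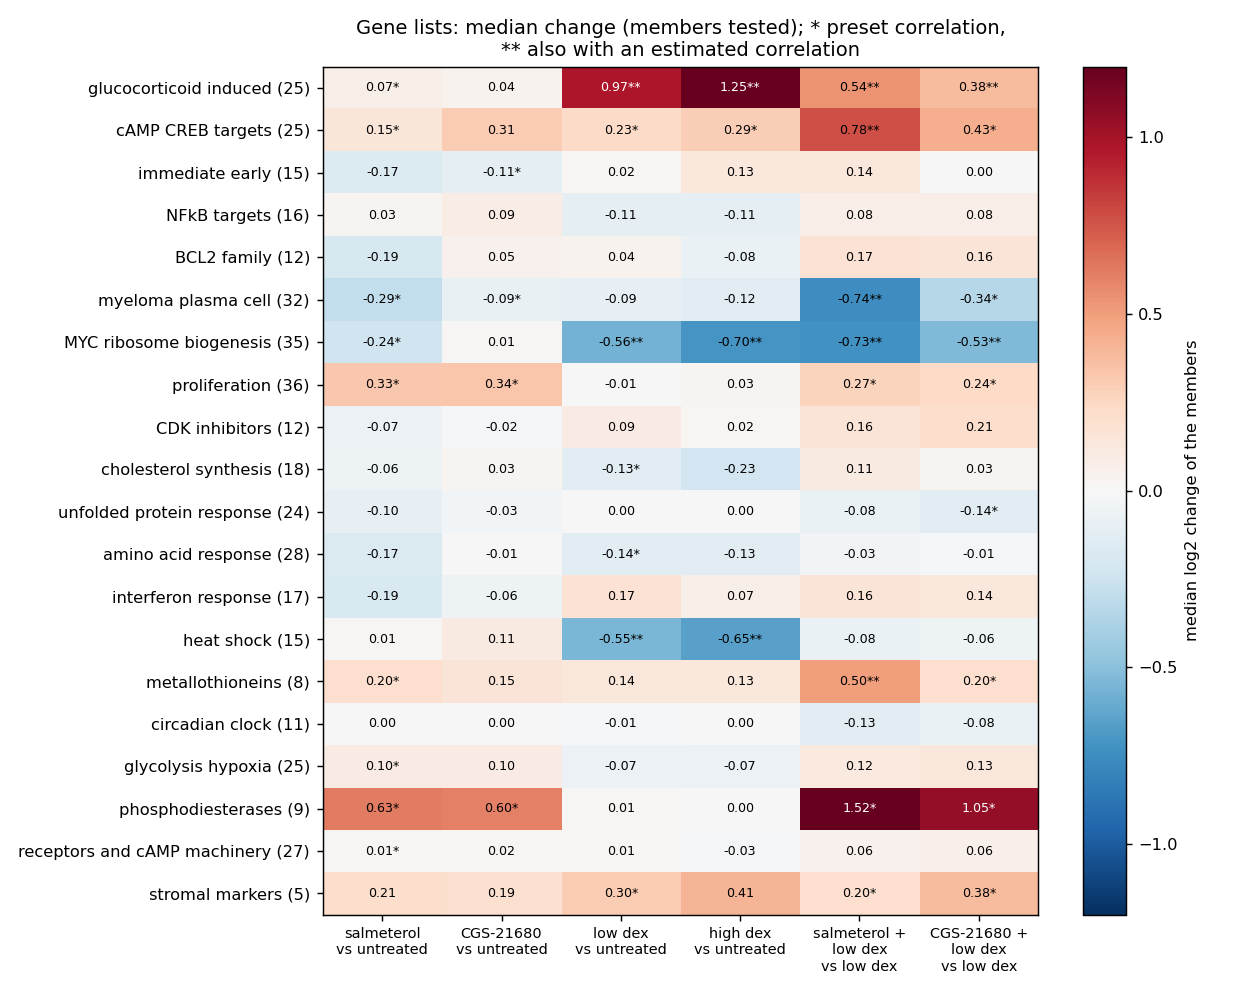
Median log2 change of the tested members of each gene list (rows, number tested in brackets) in 6 comparisons (columns); 1 asterisk marks camera's preset correlation and 2 also an estimated correlation. The median of the MYC and ribosome biogenesis list is −0.564 with low dexamethasone and −0.729 with salmeterol added to it.

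Responses to each agonist without and with dexamethasone were measured on separate arrays and against separate controls. For salmeterol they correlated at 0.59 across genes, with 110 genes higher and 225 lower in both (10.1 and 32 for independent lists) and 15 in opposite directions. For CGS-21680 the correlation was 0.47, with 24 and 17 genes (0.631 and 0.411) and 1 opposite. Beside dexamethasone, where they shared the low dexamethasone arrays, the agonists' changes correlated at 0.864 (0.501 for unchanged groups, covariance 0.177 against 0.0231), with 149 genes higher and 145 lower with both (10.3 and 12.4 for independent lists). Part of that excess may come from the shared controls. Salmeterol with dexamethasone differed from CGS-21680 with dexamethasone in 112 genes: 63 were lower with CGS-21680, among them WFDC21P (−5.37, at least 16.5-fold), FGL2 (−4.55 ± 0.389, adjusted p = 0.00073), CHST2 (−3.84), SAT1 (−2.71) and IRAK2 (−2.63, at least 2.41-fold), and 49 were higher, MYC among them (1.13 ± 0.123, adjusted p = 0.0025). That count was 42 without the salmeterol combination's replicate 1, 56 without its replicate 2 and 53 without the CGS-21680 combination's replicate 1.

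**Figure D4:**
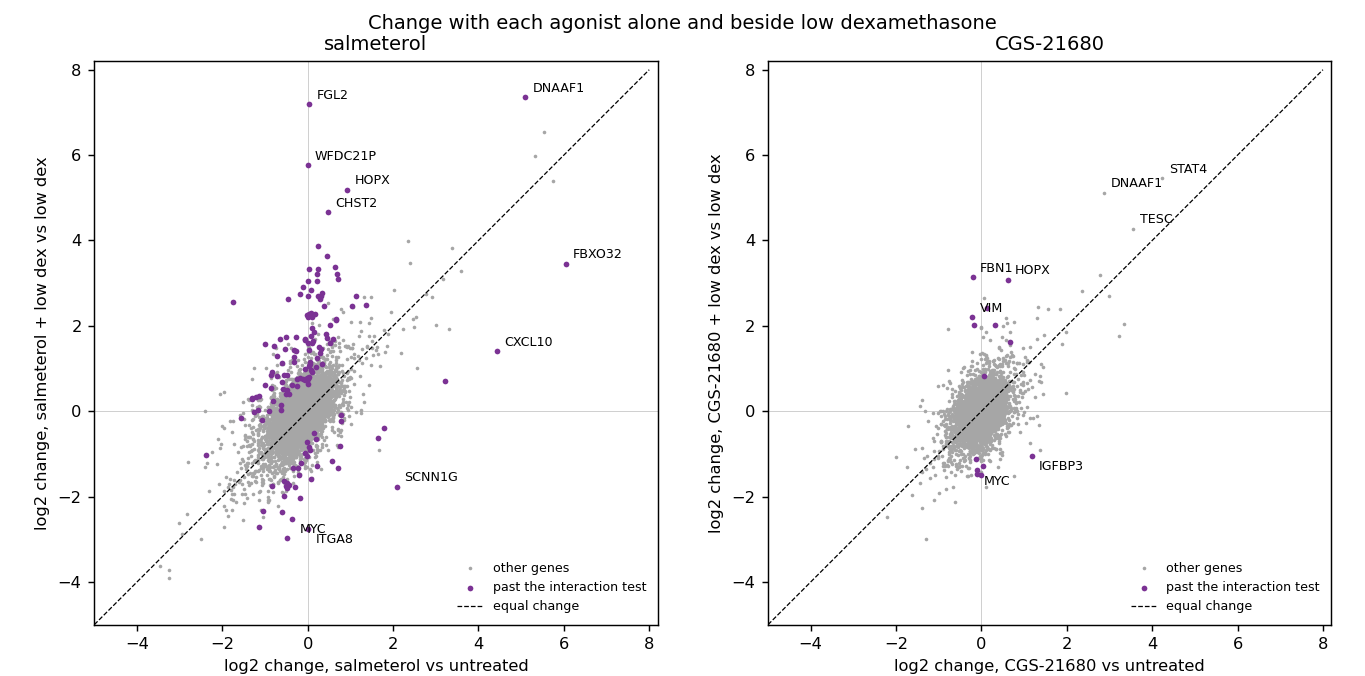
Log2 change of each of 9301 genes with an agonist alone (x axis, against untreated) and with the agonist beside low dexamethasone (y axis, against low dexamethasone), salmeterol left and CGS-21680 right; purple points passed the interaction test and the dashed line marks equal change. FGL2 lies at 0.04 alone and 7.20 beside dexamethasone for salmeterol.

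Whether dexamethasone altered the response to an agonist was tested as an interaction. For salmeterol 150 genes passed, 111 of them with a higher and 39 with a lower change beside dexamethasone. FGL2 (7.16 ± 0.55, adjusted p = 0.00052), WFDC21P (5.76 ± 0.299), HOPX (4.26 ± 0.347) and CHST2 (4.18 ± 0.447) were among the largest gains that passed in every leave-out in which they were tested, and the sodium channel subunit gene SCNN1G (−3.87), ITGA8 (−2.77, with 1 of 3 probe sets of opposite sign and a mean of −1.82) and PCDH1 (−2.51) among the largest losses that did. FGL2, WFDC21P and HOPX lay below a log2 level of 4 on every array of the 3 groups without the combination, so their exact sizes depend on the floor. With levels below 4 raised to 4 the interactions were 5.61, 4.05 and 3.97 in that order. The errors and adjusted p-values of FGL2, WFDC21P and HOPX depend on the floor too. WFDC21P lay at exactly 2.286 on every array of untreated cells, each agonist alone and each dexamethasone dose. Those arrays add no spread to its error. The interaction of MYC was −2.15 ± 0.174 (adjusted p = 0.00054). The interaction of BCL2L11 was 0.21 (adjusted p = 0.7), of IRF4 −0.44 (adjusted p = 0.27) and of TSC22D3 1.09 (adjusted p = 0.22), so that their changes beside dexamethasone and alone could not be told apart by this test. TSC22D3 did pass with the mean of its probe sets (1.70, adjusted p = 0.0117), and without CGS-21680 replicate 1 (0.0224) or 2 (0.0223). Of the lists, ribosome biogenesis genes passed with either correlation (4 of 35 lower, 12 adjusted over the list alone; median −0.546; adjusted p = 0.00373 with an estimated correlation). Camera called 6 more at the preset correlation alone: myeloma genes as lower (4 of 32, 8 adjusted over the list alone; adjusted p = 0.105 with an estimated correlation) and 5 lists as higher. These were metallothioneins (3 of 8, also adjusted over the list alone; adjusted p = 0.131 with an estimated correlation), glucocorticoid-induced genes (4 of 25 higher; adjusted p = 0.105 with an estimated correlation) and cyclic AMP targets (5 of 25 higher; adjusted p = 0.198 with an estimated correlation). The others were immediate early genes (4 of 15 higher, 1 lower; adjusted p = 0.246 with an estimated correlation) and cyclin-dependent kinase inhibitors (1 of 12 higher; adjusted p = 0.338 with an estimated correlation). Adjusted over the list alone the counts of these last 4 were 9 and 2, 7 and 0, 7 and 1, and 2 and 1. The number of interaction genes was 82 without untreated replicate 1, 91 without untreated replicate 2, 99 and 93 without low dexamethasone replicates 1 and 2, and 97 without either array of the combination. Quantile normalization gave 160 genes, 59 of them lower, so that the share of higher genes was 63.1% in place of 74%.

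For CGS-21680, 14 genes passed the interaction, 8 higher and 6 lower, led by FBN1 (3.34 ± 0.251, adjusted p = 0.0021, or 3.14 with levels below 4 raised to 4), with the ribosome biogenesis gene WDR3 among the lower (−1.49 ± 0.135, adjusted p = 0.0055). Ribosome biogenesis genes (2 of 35 lower, 9 adjusted over the list alone; median −0.602; adjusted p = 0.00274 with an estimated correlation) and glucocorticoid-induced genes (0 of 25, 5 higher adjusted over the list alone; adjusted p = 0.0458 with an estimated correlation) passed as lists. Cyclic AMP targets and myeloma genes were called at the preset correlation alone (adjusted p = 0.191 with an estimated correlation for both). The count was 2 without untreated replicate 1 and 4 without untreated replicate 2. It was 8 without salmeterol replicate 1, 7 without CGS-21680 replicate 1, 9 and 7 without low dexamethasone replicates 1 and 2, and 6 without either array of salmeterol with dexamethasone.

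Against untreated cells, salmeterol with low dexamethasone changed 2288 genes (1018 higher, 1270 lower) and CGS-21680 with low dexamethasone 1468 (712 higher, 756 lower). DDIT4 rose by 9.27 and 8.97, TSC22D3 by 8.12 and 7.88, DNAAF1 by 7.85 and 5.61, FBXO32 by 7.07 and 5.37, and BCL2L11 by 2.77 ± 0.112 and 2.49 ± 0.112, in that order. STAT4 rose by 5.47 with CGS-21680 and FGL2 by 7.27, at least 48.7-fold, with salmeterol. In the same order the falls were −5.66 (at least 31.4-fold) and −4.75 for C11orf96, −4.66 and −3.42 for ITGA8, −4.43 and −3.65 for TFRC, −3.18 and −2.61 for IRF4, −2.97 and −1.84 for MYC, and −1.98 and −1.25 for MAF. For TFRC 1 of 3 probe sets had the opposite sign in both. The mean of the probe sets gave −2.65 and −2.28 for TFRC, 3.97 and 2.80 for DNAAF1, and 3.27 for FBXO32 with CGS-21680. CCL4 (−4.75) and CCDC86 (−3.84) fell with salmeterol, and STON2 (−3.57, at least 3.7-fold) and FRMD6 (−3.39) with CGS-21680. BCL2 passed as higher with CGS-21680 (0.73) in the fit of all arrays, and did not pass with salmeterol (0.57). With CGS-21680 it did not pass with the mean of its probe sets (0.35, adjusted p = 0.058) or with no filter (adjusted p = 0.0986). Nor did it pass there without untreated replicate 1 or 2, or without replicate 1 or 2 of the combination. With salmeterol BCL2 did pass with the mean of its probe sets (0.47, adjusted p = 0.0122) and the stricter filter (0.0464). It also passed there with quantile normalization (0.0304) and the replicate block (0.0116). The counts were 1512 without untreated replicate 1 and 1485 without the combination's replicate 1 for salmeterol, and 861 and 925 without untreated replicates 1 and 2 for CGS-21680.

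The combinations were also set against the high dose of dexamethasone, 2 µM in place of 25 nM. With salmeterol 1358 genes differed, 586 higher and 772 lower. DNAAF1 was higher by 7.51, FGL2 by 7.25 (at least 48.7-fold), STAT4 by 6.70, TESC by 6.12, TSC22D3 by 1.66 ± 0.245 (adjusted p = 0.0022) and BCL2L11 by 1.51 ± 0.112 (adjusted p = 4.2e-05), while MYC lay at −2.15 ± 0.123 and IRF4 at −1.92 ± 0.108 relative to the high dose. With CGS-21680 253 genes differed, 120 higher and 133 lower. The differences were STAT4 by 5.60, DNAAF1 by 5.27, TESC by 4.40, HOPX by 3.32 (at least 3.61-fold), FBN1 by 3.06 and BCL2L11 by 1.23 ± 0.112 (adjusted p = 0.00062, and 0.0821 for the mean of its probe sets), IRAG2 by −2.19, OSBPL1A by −2.15, IRF4 by −1.35 and MYC by −1.02 ± 0.123 (adjusted p = 0.0027). The mean of the probe sets gave 3.77 and 2.60 for DNAAF1 in that order, −1.27 for IRF4 with salmeterol and −1.23 for OSBPL1A with CGS-21680. The first count was 829 without high dexamethasone replicate 2, 687 and 886 without the combination's replicates 1 and 2. The second was 617 and 133 without high dexamethasone replicates 1 and 2, and 144 without the combination's replicate 2.

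NF-kappaB targets, the BCL2 family, cyclin-dependent kinase inhibitors, the interferon response and the circadian clock were called by camera in 0 of the 6 comparisons with single treatments or added agonists, with smallest adjusted p-values of 0.123, 0.243, 0.125, 0.408 and 0.337. Their members passed singly 24, 19, 7, 18 and 8 times over those comparisons. Fry, which does not compare a list with other genes, called the BCL2 family as higher with low (adjusted p = 0.0146) and high dexamethasone (0.00795) and with salmeterol (0.00581) or CGS-21680 (0.0287) added. It called the interferon response as higher with low (0.0169) and high dexamethasone (0.0313), the kinase inhibitors as higher with salmeterol added (0.0111) and the circadian clock as lower with salmeterol alone (0.028). Over the 6 comparisons, in the order described, fry called 12, 3, 7, 9, 11 and 10 of 20 lists. In the BCL2 family 4 of 12 rose with high dexamethasone and 1 fell. Of the T cell markers 2 genes were tested, of the myeloid markers 0, and of the erythroid and platelet markers 3, too few for a list test. The T cell marker TRAT1 was the 1 of these to pass in any of the 6, at −1.87 when salmeterol was added to dexamethasone, and it did not pass without low dexamethasone replicate 1 (adjusted p = 0.0803) or 2 (0.0971), or without the combination's replicate 1 (0.0771) or 2 (0.095), or with no filter (0.0848). The glucocorticoid receptor gene NR3C1 lay between −0.38 (adjusted p = 0.27) with salmeterol added to dexamethasone and 0.21 (adjusted p = 0.91) with CGS-21680 alone.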

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

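Results are listed here because the response to an agonist differed between cells without and with low dexamethasone by the interaction test itself. For salmeterol 150 genes passed and for CGS-21680 14. The largest for salmeterol were FGL2 (7.16), WFDC21P (5.76), SLC19A2 (4.33), HOPX (4.26) and CHST2 (4.18), and SCNN1G (−3.87), CXCL10 (−3.03), ITGA8 (−2.77), FBXO32 (−2.59) and PCDH1 (−2.51). FGL2, WFDC21P and HOPX lay below a log2 level of 4 on both arrays of each group without the combination, and with levels below 4 raised to 4, a value added after the results had been seen, they had 5.61, 4.05 and 3.97. Of all these SLC19A2 did not pass in 11 and CXCL10 in 12 of the 14 fits that each left out 1 array, with adjusted p up to 0.126 and 0.181. FBXO32 did not pass without untreated replicate 1 (adjusted p = 0.0635), salmeterol replicate 2 (0.0695), low dexamethasone replicate 2 (0.0729), or the combination's replicate 1 (0.0719) or 2 (0.0593), and 2 of its 6 probe sets had the opposite sign (mean −0.82, adjusted p = 0.163).

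For CGS-21680 the largest were FBN1 (3.34), HOPX (2.46), VIM (2.41), SV2C (2.27) and AKAP14 (2.21), and IGFBP3 (−2.22), WDR3 (−1.49), FBXL12 (−1.38), CCDC86 (−1.32) and MYC (−1.28). With levels below 4 raised to 4, FBN1 had 3.14, HOPX 1.85 and AKAP14 0.95, each having lain below 4 on both arrays of untreated cells and of CGS-21680 alone. VIM, IGFBP3 and FBXL12 did not pass without untreated replicate 1 (adjusted p = 0.0846 each), and the last 2 also not without untreated replicate 2 (0.0581 and 0.0644). CCDC86 did not pass without untreated replicate 1 (0.0848) or 2 (0.121), CGS-21680 replicate 1 (0.0596), or low dexamethasone replicate 1 (0.0686) or 2 (0.0681). HOPX was lost in 9 leave-outs, SV2C in 9, AKAP14 in 10 and MYC in 11, with adjusted p up to 0.172, 0.098, 0.158 and 0.172.

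For the 3 patterns weighed next, 5 tests were chosen after the results had been seen. These are whether a single array sets the counts, whether a single array sets the ribosome biogenesis fall, whether the untreated arrays stand low, the measurement with separate control arrays, and the splits balanced by replicate number. The first pattern is that salmeterol changed more genes beside low dexamethasone (1341) than alone (555). Levels near the floor do not account for most of the interaction genes, since 80.7% of them (121 of 150) had a mean log2 level of at least 4 in all 4 groups. The other genes called only beside dexamethasone were not examined for the floor, so for the counts it is left open. A single array could contribute and is left open: the smallest ratio of the counts over the 8 arrays left out was 1.47 (725 against 493 without the combination's replicate 1), but leaving an array out also weakens the comparison it belongs to. A larger response per gene was measured on 378 genes picked on the CGS-21680 arrays against the untreated and low dexamethasone arrays together, where the median interaction in the picked direction was 0.287 (95% bootstrap interval 0.237 to 0.35, over genes that are not independent). Those control arrays also enter the salmeterol changes, so as many genes were picked with 1 replicate of the controls and measured with the other, which gave 0.211 and 0.282.

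The second pattern concerns the MYC and ribosome biogenesis list. Its genes fell more with salmeterol and dexamethasone together than the separate changes add up to, by a median of −0.546. A single array is unlikely to set it, since the median closest to 0 over the 8 arrays left out was −0.466. Saturation of bright probe sets in the single treatments would tie the interaction to the untreated level, and the rank correlation across the 35 genes was 0.12. With separate control arrays for each agonist, the interactions with salmeterol and with CGS-21680 correlated at 0.73 across the 35 genes (0.3 across all genes), and 32 genes lay below 0 in both. This is consistent with a change that follows either agonist beside dexamethasone, although the low dexamethasone and untreated groups supplied 1 array to each interaction.

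The third pattern is that the proliferation list lay higher with either agonist, by a small amount. Of 225 exact splits within the dexamethasone and other arrays, 1 had a difference as large, a share of 0.0044 and the smallest value possible. Replicate 1 lay above replicate 2 in 6 of 7 groups, and over the 81 splits balanced by replicate number the share was 0.0123, again 1 split. The list was singled out among 20 on these same arrays, with no allowance for that choice, so the splits cannot decide about chance. Scaling between arrays and untreated arrays standing low are unlikely: after quantile normalization the smallest of 4 list medians minus the median of all genes was 0.233, and beside dexamethasone, on other controls, the smaller list median was 0.242. With an estimated correlation the list passed in 0 of these 4 comparisons, although 33, 34, 30 and 30 of its 36 members lay above 0.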

How the results depend on the processing

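The rule named 552 values of 153 genes, of which 406 passed the limma test. Of those 406, 260 were tested and passed with any 1 of the 14 arrays left out, 291 under all 6 other settings that used all arrays, and 244 under both. A further 9 and 14 passed wherever tested but fell below the filter in some of these fits. Against the fit reported, 541 of the 552 values had the same call after quantile normalization, 547 with the variance trend and robust moderation, 538 with the replicate number as a block, 515 of the 518 still tested with the stricter filter, 477 with no filter and 491 with the mean of a gene's probe sets. The mean of the probe sets reversed VEGFA with salmeterol to −0.0697, since its 2 probe sets differed in sign (−0.9 and 0.761). A value that passed in neither fit also counts as the same call. With only the arrays of a comparison, 261 of the 552 had the same call. Of the 406 that passed, 291 no longer did, since that fit has fewer degrees of freedom. Levels near the floor limit what can be measured, as changes there are compressed.

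With no filter 19775 genes were tested, and the cause of the changed counts was not tested. The count was then 281 for low and 497 for high dexamethasone, 977 for CGS-21680 with dexamethasone against untreated, 24 for the CGS-21680 interaction, 14 for high against low dexamethasone and 85 for CGS-21680 against salmeterol. The mean of the probe sets gave 22 for the CGS-21680 interaction and 1 for high against low dexamethasone. The replicate block gave 22 for the CGS-21680 interaction and 72 for CGS-21680 against salmeterol, and the cause of these was not tested. Of 21 pairs of groups, 12 had deviations from the group mean that correlated above 0.1 by replicate number (median 0.11, from −0.17 to 0.26), so a weak effect shared by replicate number cannot be excluded.

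With only the arrays of the comparison, the count was 5 for salmeterol, 0 for CGS-21680, 12 for low and 2 for high dexamethasone against untreated. Against low dexamethasone it was 549 for salmeterol and 0 for CGS-21680 added to it. It was 240 for CGS-21680 with dexamethasone against untreated, 0 for the CGS-21680 interaction, 0 for the agonists against each other without and 0 with dexamethasone, and 220 and 0 for the salmeterol and CGS-21680 combinations against high dexamethasone.

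With an estimated correlation, camera called 0 lists for salmeterol in place of 9, 0 for CGS-21680 in place of 4, 3 for low dexamethasone in place of 7, 5 for salmeterol added to it in place of 8 and 2 for CGS-21680 added to it in place of 9. Leaving out 1 array gave 8 to 9, 1 to 5, 4 to 7, 7 to 9 and 6 to 9 lists in that order, and 4 to 5 for high dexamethasone.

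Over the arrays left out in turn, the gene counts ranged from 213 to 571 for salmeterol, 11 to 52 for CGS-21680, 187 to 448 for low and 342 to 1066 for high dexamethasone. They ranged from 725 to 1417 for salmeterol and 99 to 287 for CGS-21680 added to low dexamethasone. Against untreated cells the combinations gave 1485 to 2340 and 861 to 1550. The interactions gave 82 to 152 for salmeterol and 2 to 16 for CGS-21680. The other ranges were 0 to 60 for high against low dexamethasone, 8 to 70 and 42 to 116 for CGS-21680 against salmeterol without and with dexamethasone, and 687 to 1462 and 133 to 617 for the salmeterol and CGS-21680 combinations against high dexamethasone.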

Other observations

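Some genes reached a log2 level of at least 6 on both arrays of salmeterol with low dexamethasone while lying below 4 on every array of untreated cells, salmeterol alone and low dexamethasone alone. There were 5, chosen after their values were seen: AKAP14, which encodes an anchoring protein of protein kinase A, FGL2, HOPX, the transcription factor gene KLF5, and WFDC21P. Their levels with salmeterol and dexamethasone were 6.098 and 6.414 for AKAP14, 9.453 and 9.757 for FGL2, 7.879 and 8.052 for HOPX, 6.01 and 6.567 for KLF5, and 7.825 and 8.268 for WFDC21P. With CGS-21680 and dexamethasone they were 4.842 and 5.061, 4.244 and 5.861, 5.48 and 6.226, 4.029 and 4.277, and 2.305 and 3.04. By the same rule there were 0 such genes with CGS-21680 and dexamethasone. Against untreated cells alone there were 0 with salmeterol, 0 with CGS-21680, 1 with low dexamethasone (the adaptor gene GRB14) and 2 with high dexamethasone (GRB14 and CXCL13).

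SGK1, chosen after its values were seen, encodes a kinase that glucocorticoids induce in many cells, and fell with dexamethasone alone: by 0.60 on the log2 scale at the low dose (adjusted p = 0.0298) and 0.67 at the high dose (adjusted p = 0.0128). It rose when salmeterol (2.75) or CGS-21680 (0.99) was added to the low dose. The falls of SGK1 were not followed over the arrays left out or the other settings.

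Probe sets that pass the filter but carry several gene symbols or none were tested apart from the genes. There were 2287, of which 25 control probe sets were left out and 2262 tested. Of the tested probe sets 72 changed with salmeterol, 7 with CGS-21680, 51 with low and 105 with high dexamethasone, 193 with salmeterol added to low dexamethasone and 40 with CGS-21680 added to it. The interactions had 16 for salmeterol and 2 for CGS-21680, and 1 differed between the doses of dexamethasone.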
